A study of Mus musculus with 6 samples.

How the data were processed

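The values were taken from a series-wide table of 6 one-colour Affymetrix arrays, 3 of D3.5 and 3 of D4.5 luminal epithelium. Its array columns hold linear intensity values that the authors deposited, with totals between 8.99e+06 and 1.04e+07 per array. The software, summary method and genome build are not given in the sources used here. The deposited table also gives a p-value and a ratio per row as the authors' own comparison. On all 35556 rows the deposited p-value equalled a Welch test of the linear values, the deposited fold change equalled the ratio of the day means, and the deposited SD of D3.5 equalled the SD of the D4.5 values (tolerance 1e-06), so these columns were not used. A second deposited table of the same intensity values differed on 1 row, which has no gene symbol.

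Genes were named by the symbol column of the deposited table. Of the rows 25070 held 1 symbol, 2 held several, 10420 none, 38 were blank and 26 had been turned into dates; the rows with 1 symbol gave 21740 genes, 19994 of them with 1 row and 1746 with several. Of the symbols 17961 are current in the RefSeq gene table of assembly GRCm38.p6, 2757 matched as a synonym of 1 gene and 1022 did not match; that table was used for names alone. Identifiers were not used, since 6551 successive rows carry identifiers that rise by exactly 1 in the order of the symbols. Day means correlated with r = 0.939 across genes with 1 row, but with -0.023 across rows without a symbol, and the deviations of rows from the mean of their symbol correlated with -0.006 between days while within a day they correlated with at least 0.947. Rows that share a symbol are therefore not paired between the days. The mean of all rows of a symbol, which does not depend on their order, was used per gene, in place of the row with the highest mean that had been planned before the data were examined; this was decided before any test was run. Rows without exactly 1 symbol were left out. Neighbouring genes showed no sign of exchanged values: 3 pairs of adjacent rows looked exchanged, against 2 to 13 pairs of rows 2 to 20 apart.

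Array medians of log2 intensity were 6.76 to 6.89 on D3.5 and 6.30 to 6.33 on D4.5, over the planned limit, so log2(intensity + 16) values were quantile normalized over all rows. Among genes with 1 row, 356 to 1092 values were exactly equal between arrays of D3.5, 5 to 24 between arrays of D4.5 and 0 between days. No detection calls were used and no filter was set. A gene was said to be at the level of receptor genes on a day when its mean lay at or under the 95th percentile of chemosensory receptor genes; arrays have no read depth, and their number limits the precision.

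D4.5 was compared with D3.5 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 21740 genes, a threshold of 0.05 and, as a second criterion, at least 2-fold. Adjusted p-values are from that fit. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The 38 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 38 lists. Camera asks whether the genes of a list change apart from other genes. The fry test asks whether they change at all, so its direction depends on the scaling between the days. The genes named are, as fixed before the data were examined, the 12 largest rises and 12 largest falls with adjusted p under 0.05 and no overlap of the days, leaving out clone names, every measured implantation regulator, and from each other list up to 2 genes per direction with the smallest p (the 1 with the smallest p where none passed). Some genes that this rule selects are not reported here, and no others were put in their place. On data simulated with the spread of these arrays over 21740 genes, the fit recovered 42% of 50 genes changed by 0.5 on the log2 scale, 88% of 50 changed by 1, 96% of 50 changed by 2 and 100% of 50 changed by 4, and 6.86% of its calls were false. The simulated noise was independent between genes and held no difference in processing between the days. These rates therefore do not describe calls that such a difference would give in the real arrays. Far fewer genes were changed in the simulation than the 9651 that passed in the real arrays. The same adjusted p was therefore a stricter cut in the simulation, and the rates do not carry over directly.

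Alternatives planned before the data were examined were median centring, constants of 1 and 64, the genes above the median level, eBayes with trend and robust, array weights, the replicate number as a block and each array left out in turn. The values as deposited, the row with the highest mean and the genes with 1 row were added after seeing the data.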

Results

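Transcripts of the mouse uterine luminal epithelium, the cell layer that lines the uterine cavity and that an implanting embryo meets first, were measured on gestation day 3.5 (D3.5), before implantation, and on gestation day 4.5 (D4.5), after it. The mice had a mixed background of the C57BL6 and 129svj strains. The epithelium was taken off the uterus as sheets with dispase and gentle scraping. Each day had 3 one-colour Affymetrix arrays, and each array held biotin-labelled cRNA made from 1 µg of total RNA. The median deposited intensity was between 108.6 and 118.4 on the D3.5 arrays and between 78.9 and 80.2 on the D4.5 arrays. Values below are log2(intensity + 16) after quantile normalization, as mean ± SD over the 3 arrays of a day, and changes are log2 fold changes of D4.5 minus D3.5 ± SE. The labels do not say whether the arrays of a day came from separate animals, so p-values measure the spread between these samples, which may be technical.

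The comparison of D4.5 with D3.5 asked which genes of the luminal epithelium differ between the uterus before and after implantation. Among the largest rises on D4.5 was that of Prap1, which encodes a secreted proline-rich acidic protein. It rose 22.8-fold, from 7.27 ± 0.14 to 11.78 ± 0.27 (adjusted p = 8.48e-06). The protease gene Mmp7 (matrilysin) rose by 4.48 ± 0.21 (3.88 with a constant of 64 in place of 16), and Gabrp, a subunit of the GABA-A receptor, by 4.49 ± 0.18 (3.87), both from the level of genes that this epithelium is not known to use. Among the largest falls were those of Npl, a lyase of sialic acid breakdown (35.9-fold, from 12.10 ± 0.17 to 6.94 ± 0.32, adjusted p = 8.48e-06), and of Calb1, the calcium-binding protein calbindin (18.8-fold, from 11.86 ± 0.10 to 7.63 ± 0.36). Pgr, the progesterone receptor, fell 8.87-fold, from 10.31 ± 0.20 to 7.16 ± 0.39 (adjusted p = 4.28e-05).

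Among the 12 largest rises, Ggh, a hydrolase of folate polyglutamates, changed by 4.49 ± 0.26, Tll1, a tolloid-like metalloprotease, by 4.33 ± 0.30, and Ttpa, the vitamin E transfer protein, by 4.25 ± 0.15. Atp6v0d2, a subunit of the vacuolar proton pump, rose by 4.47 ± 0.64 to 12.33 ± 0.04. Its D3.5 arrays spread widely (7.86 ± 1.50), since replicate 2 stood at 9.57 and replicates 1 and 3 at 6.73 and 7.28, and without replicate 2 the change was 5.35. The proprotein convertase gene Pcsk6 (3.90 ± 0.13), Ifitm6 of the interferon-induced transmembrane family (3.88 ± 0.35), the mitochondrial calcium-binding protein gene Efhd1 (3.87 ± 0.13), Olfm1 (3.77 ± 0.14) and the lactate and pyruvate transporter gene Slc16a1 (3.75 ± 0.16) completed this group. Among the 12 largest falls, the adhesion receptor gene Gpr128, now named Adgrg7, changed by -4.02 ± 0.20, and the glucose transporter gene Slc2a3 by -3.61 ± 0.18. Fxyd4, a regulator of the sodium pump (-3.53 ± 0.16), Il17rb, an interleukin receptor subunit (-3.52 ± 0.18), and Cbr2, a carbonyl reductase (-3.46 ± 0.17), fell by similar amounts. Tmem158 (-3.38 ± 0.17), the acyl-CoA thioesterase gene Acot7 (-3.25 ± 0.13), the secreted phospholipase gene Pla2g10 (-3.23 ± 0.14) and the glycosyltransferase gene B3gnt5 (-3.22 ± 0.27) followed. The highest adjusted p among these 24 genes was that of Atp6v0d2 (0.00152).

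**Figure D1:**
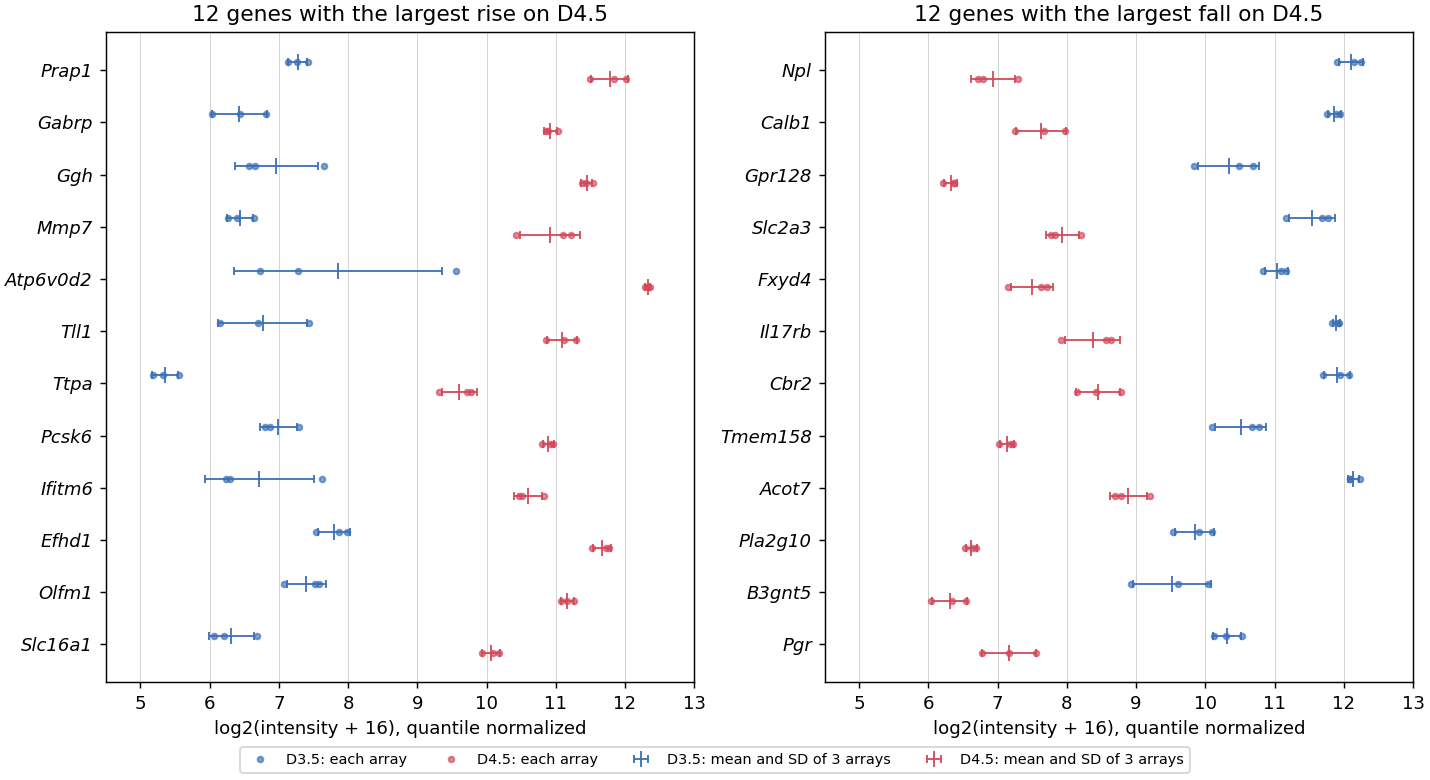
Levels of the 12 genes with the largest rise and the 12 with the largest fall on D4.5, with gene names on the vertical axis and log2(intensity + 16) after quantile normalization on the horizontal axis. Points are single arrays, ticks and whiskers the mean and SD of the 3 arrays of D3.5 (blue) and D4.5 (red); no gene's days overlap, and Atp6v0d2 has the widest spread on D3.5 (7.86 ± 1.50).

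Of 21740 genes tested with limma, 1195 had an adjusted p under 0.05 and a change of at least 2-fold, of which 660 rose and 535 fell. Without the size criterion 9651 genes passed, 3914 higher and 5737 lower on D4.5, a balance that turned with scaling (6093 higher and 4264 lower with median centring, 2483 and 13431 in the values as deposited). Chemosensory receptor genes, which this epithelium is not known to use, gave the background of the comparison. Of 1209 such genes 371 passed the adjusted p and 3 passed with 2-fold, 95% of their changes lay between -0.60 and 0.33, and 95% of their mean levels lay under 6.58 on D3.5 and 6.40 on D4.5. A named change between -0.60 and 0.33 is thus not set apart from this background by its adjusted p alone. With median centring in place of quantile normalization, 1276 of the 1572 genes past both criteria were higher on D4.5 (81.2%, against 55.2%), and in the values as deposited 504 of 1556 were (32.4%). Exactly equal values occurred between arrays of a day and never between days, and day and array processing cannot be told apart. Gabrp, Mmp7, Ttpa and Slc16a1 lay at the level of receptor genes on D3.5, as Gpr128 and B3gnt5 did on D4.5, and their folds depend on the constant added before the logarithm. With 64 in place of 16 the change was 3.21 for Ttpa (4.90 with 1), 3.12 for Slc16a1, -3.39 for Gpr128 and -2.62 for B3gnt5.

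Regulators of implantation moved in both directions. Of 35 measured members of this list, 11 rose, 11 fell and 13 did not pass (12 rose and 13 fell when adjusted over the list alone). Besides Atp6v0d2, the rises were led by Cyp26a1, which breaks down retinoic acid (from 9.11 ± 1.12 to 11.94 ± 0.03, adjusted p = 0.0031), Spp1, the secreted adhesion protein osteopontin (2.82 ± 0.32), Lifr, a receptor subunit for leukaemia inhibitory factor (2.60 ± 0.31), and Ereg, an EGF-family ligand (2.59 ± 0.40, 1.99 with array weights). The kinase gene Sgk1 rose by 1.37 ± 0.15, Erbb3 by 0.89 ± 0.10, the EGF-family ligand gene Hbegf by 0.82 ± 0.15, the activin subunit gene Inhbb by 0.77 ± 0.09, Lif itself by 0.63 ± 0.15 and the diamine oxidase gene Abp1 by 0.49 ± 0.09. The calls of Lif and Abp1 were lost in the values as deposited. The falls were led by Lpar3, a lysophosphatidic acid receptor (from 10.36 ± 0.30 to 7.83 ± 0.17, adjusted p = 4.31e-05), the transcription factor genes Gata2 (-1.95 ± 0.08) and Msx1 (-1.78 ± 0.09), and Hdc, the enzyme that makes histamine (-1.50 ± 0.08).

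Smaller falls in this list followed. The phospholipase gene Pla2g4a changed by -1.23 ± 0.16, the lipoxygenase gene Alox15 by -1.23 ± 0.30 and the cyclooxygenase gene Ptgs2 by -0.83 ± 0.21. Muc1, a cell-surface mucin, changed by -0.85 ± 0.18 and Msx2 by -0.47 ± 0.13. With median centring Alox15, Ptgs2 and Muc1 no longer passed, Ptgs2 did not pass without D3.5 replicate 3, and Msx2 did not pass without D4.5 replicate 1 or without replicate 2. Calca (-0.23 ± 0.07) and Cnr1 (-0.28 ± 0.06) passed the test at the level of receptor genes on both days, Calca lost its call whichever array was left out, and Cnr1 lost it without D4.5 replicate 2. Members that did not pass were Fst (0.44 ± 0.17), Wnt7a (0.35 ± 0.18), Faah (0.14 ± 0.07), Cdh1 (0.05 ± 0.07), Hoxa10 (-0.05 ± 0.32), Ihh (-0.08 ± 0.19), Irg1, now Acod1 (-0.12 ± 0.23), Stat3 (-0.13 ± 0.11, but 0.43 and past the threshold with median centring), Areg (-0.14 ± 0.33), Klf5 (-0.21 ± 0.08), Il6st (-0.25 ± 0.21), Ptgs1 (-0.40 ± 0.22) and Egfr (-0.41 ± 0.15). Fst, Wnt7a, Faah, Cdh1, Klf5, Il6st, Ptgs1 and Egfr also passed in at least 1 alternative fit. Their lowest adjusted p over these fits ran from 0.0037 (Faah) to 0.0386 (Ptgs1). As a list the implantation regulators did not stand apart from other genes (camera adjusted p = 0.727), and their median change was -0.12 beside a mean of 0.19.

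**Figure D2:**
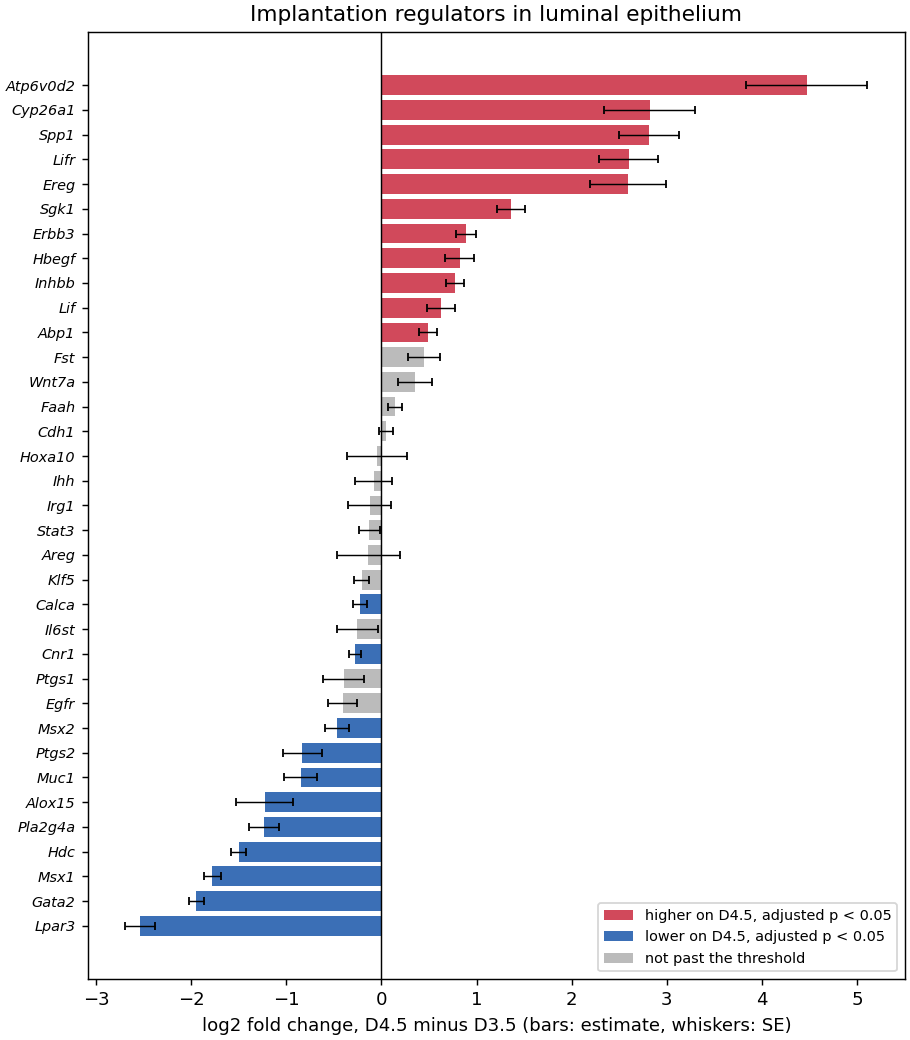
Log2 fold change of D4.5 minus D3.5 for the 35 measured implantation regulators, with gene names on the vertical axis; bars are estimates and whiskers standard errors. Red bars are the 11 that rose, blue bars the 11 that fell and grey bars the 13 that did not pass; Atp6v0d2 (4.47) and Lpar3 (-2.54) mark the ends.

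The next question was whether genes of a common function moved together. The counts of each list stand beside 45.2% of all genes other than receptor genes that passed the same adjusted p in either direction. By direction, 3914 of all 21740 genes rose and 5737 fell. Genes of the endoplasmic reticulum stress response rose as a group. Of 29 measured, 17 rose and 3 fell (20 and 4 adjusted over the list alone), with a median change of 0.49 (camera adjusted p = 9.35e-05, but 0.823 as adjusted p with an estimated correlation). Xbp1, a transcription factor of this response, rose by 1.78 ± 0.16 and the chaperone gene Hyou1 by 1.09 ± 0.09, while Sesn2 (-0.49 ± 0.10) and Syvn1, a ubiquitin ligase of protein disposal (-0.50 ± 0.12), fell, both without a call under median centring. Immediate early and stress genes were higher too. 16 of 35 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 0.00367, adjusted p = 0.823 with an estimated correlation). The median change of the list was 0.22, beside 0.20 for 18 genes often used as references. Past 2-fold, 2 rose and 1 fell. Myc rose by 2.41 ± 0.16 and Ier5 by 0.58 ± 0.09, whereas Nr4a3 (-1.03 ± 0.25) and Dusp6 (-0.31 ± 0.08) fell. With median centring the call of Nr4a3 was lost, as it was without D4.5 replicate 2, and Dusp6 stood at 0.15. Dusp6 also lost its call in the values as deposited and without 4 of the 6 arrays in turn.

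In the list for hypoxia and glycolysis 16 of 31 genes rose and 4 fell (16 and 6 adjusted over the list alone), with camera adjusted p = 0.00367 and adjusted p = 0.823 with an estimated correlation. The median change of this list was 0.22, beside 0.20 for the reference genes. The glycolytic enzyme genes Eno1 (1.22 ± 0.09) and Pfkp (1.43 ± 0.11) rose. Pfkfb3, which makes an activator of glycolysis (-1.42 ± 0.12), and the oxygen-sensing hydroxylase gene Egln1 (-1.37 ± 0.11) fell. Proteases and their inhibitors also rose as a list (21 of 48 up, 9 down; 22 and 10 adjusted over the list alone; camera adjusted p = 0.00804, adjusted p = 0.823 with an estimated correlation). Beside Mmp7, Spink3, a trypsin inhibitor, rose by 1.53 ± 0.09 from the level of receptor genes, and the inhibitor genes Timp3 (-1.87 ± 0.27) and Serpine2 (-1.84 ± 0.22) fell. In the proliferation list 8 of 43 genes rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.00901, adjusted p = 0.881 with an estimated correlation). The share that rose was close to that of all genes (3914 of 21740), a smaller share fell, and 32 of the 43 did not pass. The median change was 0.20, as for the reference genes. The DNA replication genes Pcna (0.90 ± 0.12) and Mcm7 (1.06 ± 0.15) rose and Tyms, which makes thymidylate (-1.42 ± 0.11), fell, as did Top2a (-0.67 ± 0.16). The proliferation list averaged 6.67 in D4.5 replicate 3, below the D3.5 arrays (6.74 to 6.81), and the same array had the lowest stromal, endothelial and leukocyte marker levels. The call was lost without D4.5 replicate 1 (adjusted p = 0.143) or replicate 2 (0.0704). It was also lost with median centring, with fry and in the values as deposited, where the mean of the list was -0.15 in place of 0.22. Among genes above the median level alone, the stress response of the endoplasmic reticulum was the list past the threshold, and the other 4 were not. The hypoxia list also lost its call over genes with 1 row (adjusted p = 0.133).

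**Figure D3:**
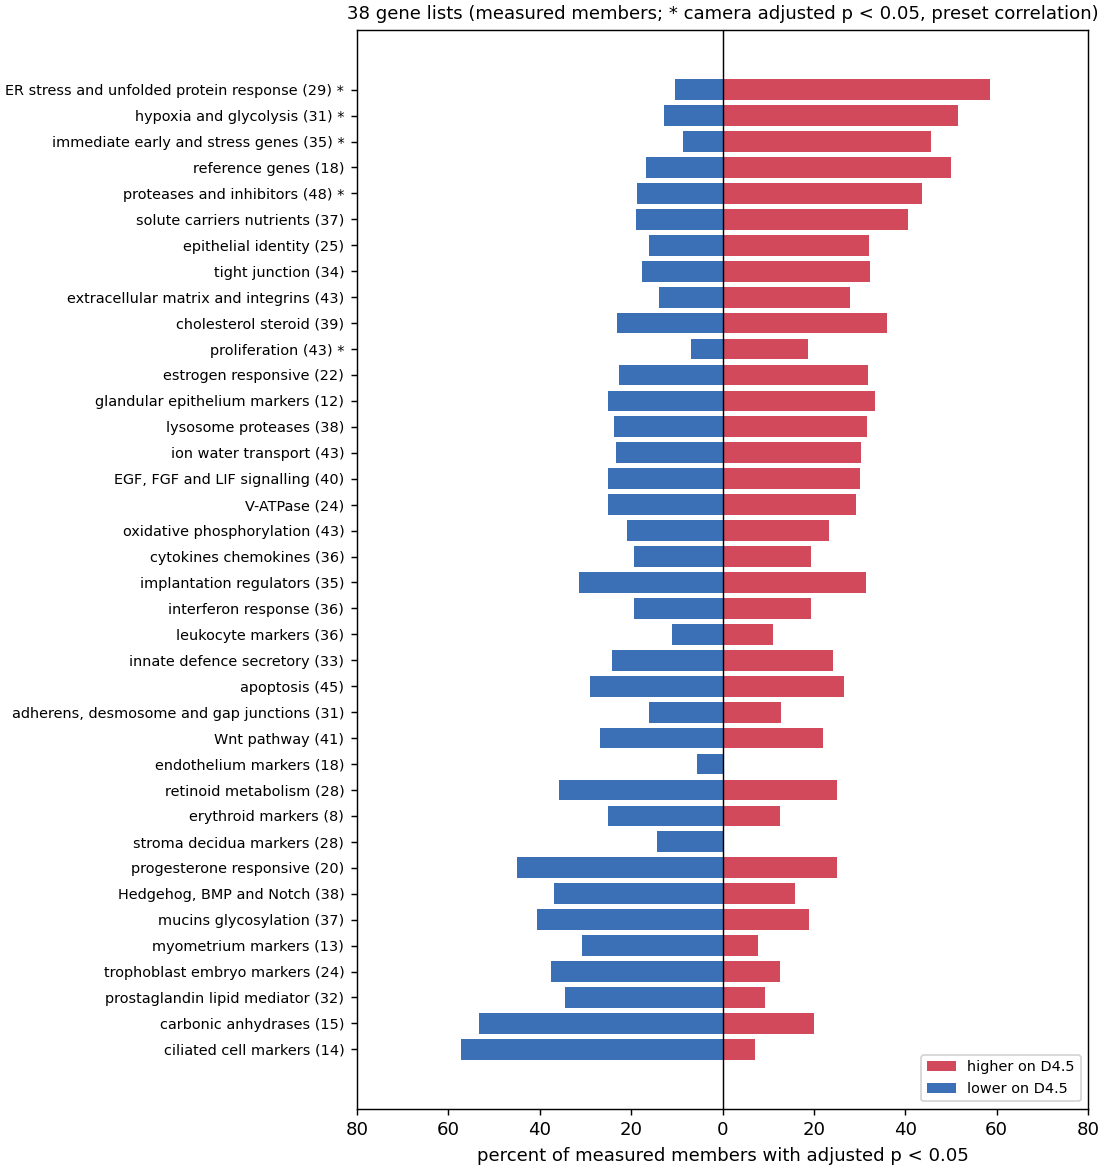
Percent of the measured members of each of 38 gene lists that passed the adjusted p of 0.05, to the right for genes higher and to the left for genes lower on D4.5; the number of measured members is in parentheses and a star marks camera adjusted p under 0.05 with the preset correlation. The 5 starred lists had more genes higher than lower, and none was past the threshold with an estimated correlation (lowest adjusted p = 0.823).

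Of 20 progesterone-responsive genes 5 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.576, fry lower with adjusted p = 0.00783). The endocytic receptor gene Lrp2 fell by 2.46 ± 0.09 on the log2 scale alongside Gata2, while the sulfotransferase gene Sult1d1 rose by 1.02 ± 0.13. Of 22 oestrogen-responsive genes 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.273, fry higher with adjusted p = 0.000255), among them the growth factor gene Fgf9 (2.88 ± 0.10), the cyclin gene Ccnd1 (1.94 ± 0.16) and Padi2, which converts arginine to citrulline (-1.60 ± 0.14). Among 32 genes for prostaglandins and related lipid mediators 3 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.557, fry lower with adjusted p = 0.00424). Ptger2, a prostaglandin receptor, rose by 1.00 ± 0.19 and Pla2g12a by 0.51 ± 0.07. Cholesterol and steroid genes (14 of 39 up, 9 down; 15 and 9 adjusted over the list alone; camera adjusted p = 0.152, fry higher with 0.0409) included rises of the steroid reductase gene Srd5a1 (1.98 ± 0.16) and of Hsd17b7 (0.89 ± 0.07), and falls of the fatty acid synthesis genes Fasn (-1.56 ± 0.08) and Acaca (-1.15 ± 0.12). Of 28 retinoid genes 7 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.727). Rdh11 (1.22 ± 0.11) and Rbp4 (0.87 ± 0.06) rose, the receptor gene Rara (-0.63 ± 0.08) fell, and Aldh1a7 (-0.82 ± 0.10) fell at the level of receptor genes on both days.

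In the list of the vacuolar proton pump 7 of 24 genes rose and 6 fell, the same counts adjusted over the list alone (camera adjusted p = 0.576). Besides Atp6v0d2, the subunit gene Atp6v0a4 rose by 1.85 ± 0.13 and Atp6ap1 by 0.71 ± 0.08, and the related subunit genes Atp6v0a1 (-1.59 ± 0.11) and Atp6v0d1 (-0.88 ± 0.11) fell. Of 15 carbonic anhydrase genes 3 rose and 8 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.273, fry lower with 0.00276). Car12 rose by 1.59 ± 0.32, Car2 (-1.91 ± 0.10) and Car5b (-2.28 ± 0.18) fell, and Car15 passed with 0.24 ± 0.07. Car15 lost its call without 5 of the 6 arrays in turn and stood at -0.15 in the values as deposited. Ion and water transport genes (13 of 43 up, 10 down; 13 and 13 adjusted over the list alone; camera adjusted p = 0.557) included the sodium-proton exchanger gene Slc9a2 (1.48 ± 0.09), the potassium channel gene Kcnq1 (1.17 ± 0.09) and the calcium pump gene Atp2b2 (-1.83 ± 0.13). Of 37 nutrient carriers 15 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.052, fry higher with 0.0486). The amino acid transporter gene Slc43a2 rose by 2.52 ± 0.12 from the level of receptor genes and the zinc transporter gene Slc39a14 fell (-1.87 ± 0.09). Of 38 lysosomal genes 12 rose and 9 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.273), with Ctsz (1.15 ± 0.09) higher and Lamp2 (from 12.10 ± 0.14 to 11.10 ± 0.05) and Hexa (-0.60 ± 0.09, no call under median centring) lower. In the list for oxidative phosphorylation 10 of 43 genes rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.292). Idh3a, a citric acid cycle gene that the list also holds, rose by 1.09 ± 0.10. Sdhd rose by 0.83 ± 0.08, and Ndufa2 (-0.86 ± 0.09) and Ndufb9 (-0.54 ± 0.06, no call under median centring) fell.

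Tight junction genes (11 of 34 up, 6 down; 11 and 9 adjusted over the list alone; camera adjusted p = 0.273) included Amot (1.28 ± 0.08), Cldn23 (0.74 ± 0.09), Jam2 (-2.48 ± 0.25) and Tjp3 (-0.67 ± 0.10). Of 31 genes of adherens junctions, desmosomes and gap junctions 4 rose and 5 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.458). The connexin gene Gjb2 rose by 2.95 ± 0.20, the desmosomal cadherin gene Dsc2 by 1.81 ± 0.09, and Dsp (-0.44 ± 0.07, no call under median centring) and Gjb5 (-0.30 ± 0.07, no call without D4.5 replicate 2) fell. Among 43 matrix and integrin genes 12 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.152). The laminin genes Lama3 (2.04 ± 0.08) and Lama1 (1.63 ± 0.11) rose, and the integrin gene Itgb6 (-1.29 ± 0.08) and Cd47 (-1.16 ± 0.12) fell. Of 37 mucin and glycosylation genes 7 rose and 15 fell (8 and 15 adjusted over the list alone; camera adjusted p = 0.449, fry lower with 0.00984). The transferase genes that start mucin-type glycans went opposite ways, Galnt3 by 1.37 ± 0.08 and Galnt1 by -1.37 ± 0.08, St3gal1 rose by 0.59 ± 0.08, and the fucosyltransferase gene Fut2 fell (-1.77 ± 0.13).

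Signalling and immune genes were likewise mixed. Of 41 Wnt pathway genes 9 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.727). Wnt7b rose by 3.52 ± 0.08 (from 7.06 ± 0.10 to 10.58 ± 0.07, adjusted p = 6.38e-06) and Kremen1 by 1.23 ± 0.08, and Lgr4 (-1.09 ± 0.10) and Tcf7l2 (-0.98 ± 0.12) fell. Of 38 genes of the Hedgehog, BMP and Notch pathways 6 rose and 14 fell, the same adjusted over the list alone (camera adjusted p = 0.727). The Notch target Hey2 (-2.43 ± 0.20) and Notch1 (-1.19 ± 0.10) fell and the ligand gene Dll4 rose by 0.75 ± 0.09. In the EGF, FGF and LIF list 12 of 40 rose and 10 fell (12 and 13 adjusted over the list alone; camera adjusted p = 0.557), with Fgf18 (-1.22 ± 0.13) and Nrg1 (-0.91 ± 0.09) lower. Cytokine and chemokine genes split evenly (7 of 36 up, 7 down, also adjusted over the list alone; camera adjusted p = 0.727). Csf1, a macrophage growth factor, rose by 2.93 ± 0.10 and Il1rn by 0.58 ± 0.07, and Il1r1 (-1.66 ± 0.27) and Tnfsf11 (-0.80 ± 0.15) fell. The call of Il1rn was lost in the values as deposited. Interferon-response genes (7 of 36 up, 7 down, also adjusted over the list alone; camera adjusted p = 0.541) included Ifit3 (3.43 ± 0.16, 2.82 with a constant of 64), Irf1 (0.78 ± 0.13), the RNA sensor gene Ddx58 (-2.05 ± 0.13) and Xaf1 (-1.16 ± 0.15). Among 33 innate defence genes 8 rose and 8 fell (9 and 9 adjusted over the list alone; camera adjusted p = 0.8), with Tlr4 (1.44 ± 0.09) higher and Cd14 (-1.45 ± 0.10) and Tlr3 (-1.02 ± 0.09) lower. Of 45 apoptosis genes 12 rose and 13 fell, the same adjusted over the list alone (camera adjusted p = 0.727). Trp53 (1.28 ± 0.10) and Bid (1.00 ± 0.11) rose, and Casp8 (-0.95 ± 0.10) and Bmf (-0.81 ± 0.09) fell. The lists of retinoid, Wnt, EGF, cytokine, innate defence and proton pump genes had a median below 0 and a mean above it, as had the apoptosis list and the ion transport list, so no direction is given for them. Of 18 genes often used as references 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.152, fry higher with 0.0444), among them Hprt1, now Hprt (0.49 ± 0.08), Pgk1 (0.68 ± 0.12) and Tbp (-0.32 ± 0.07, 0.10 with median centring).

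Markers of other cell types were compared because sheets taken by enzyme and scraping could hold other uterine cells, blood or embryo. None of the 8 marker lists passed the threshold with camera and quantile normalization. Epithelial identity genes were bright on every array, between 10.03 and 10.24 on average. Of 25 such genes 8 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.273), among them Spint1 (1.99 ± 0.22), St14 (0.82 ± 0.07), Krt19 (-1.60 ± 0.19) and Grhl2 (-1.04 ± 0.09). Stromal markers averaged 7.52, 7.82 and 7.38 on the D3.5 arrays and 7.97, 7.55 and 6.95 on the D4.5 arrays, so arrays of the same day differed more than the days. None of 28 stromal markers rose and 4 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.889), with Twist2 at -0.55 ± 0.12 (no call under median centring) and Twist1 at -0.27 ± 0.08 (no call without 5 of the 6 arrays in turn).

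Endothelial markers followed the stromal ones from array to array (7.22, 7.48 and 7.04 on D3.5; 7.55, 7.20 and 6.82 on D4.5). 1 of 18 changed, also when adjusted over the list alone, which was Sox17 (-1.06 ± 0.12), a gene that is also among the embryo markers (camera adjusted p = 0.785 for the endothelial list, median 0.01 beside a mean of -0.06). Leukocyte markers were highest in D4.5 replicate 1 (7.19) and lowest in D4.5 replicate 3 (6.64). 4 of 36 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.313), Csf1r by 0.76 ± 0.13, H2-Aa by 0.85 ± 0.20 and Lyz1 by -1.25 ± 0.16, and the calls of Csf1r and H2-Aa were lost in the values as deposited, that of H2-Aa also without D4.5 replicate 2. The leukocyte list passed as a whole without D4.5 replicate 3. Ciliated cell markers were low and stood at 6.39 to 6.51 on D3.5 and 6.03 to 6.14 on D4.5. 1 of 14 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.273). That list passed with median centring, with fry and in the values as deposited. Dnahc5, now Dnah5, a dynein gene of motile cilia, fell from 8.53 ± 0.09 to 5.88 ± 0.03 (adjusted p = 6.96e-06), Hydin by -0.46 ± 0.09, and Ccdc39 passed with 0.25 ± 0.07 (-0.21 in the values as deposited, no call under median centring or without 3 of the 6 arrays in turn). Gland markers stood at 6.63 to 6.68 on D3.5 and 6.99 to 7.12 on D4.5, with 4 of 12 up and 3 down (5 and 4 adjusted over the list alone; camera adjusted p = 0.476, median -0.01 beside a mean of 0.39, fry higher with 0.00759). Gpx3 (3.61 ± 0.27) and Spink3 rose, and Aldh1a1 (-0.89 ± 0.15) and Cxcl15 (-0.45 ± 0.09) fell. Among 24 trophoblast and embryo markers 3 rose and 9 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.476), Tead4 by 1.56 ± 0.10, Ascl2 by 0.72 ± 0.09 and Sox2 by -1.39 ± 0.14, each at the level of receptor genes on the lower day, and Ascl2 without a call in the values as deposited. Of 13 myometrial markers 1 rose and 4 fell (camera adjusted p = 0.727) and of 8 erythroid markers 1 rose and 2 fell (camera adjusted p = 0.889), the same counts adjusted over the list alone. Myocd (-0.45 ± 0.08), Synm (-0.29 ± 0.06), Tagln (0.28 ± 0.08) and Alas2 (-0.45 ± 0.11) were among those with the smallest p, and Tagln was below 0 in the values as deposited. Tagln also lost its call with median centring and without 4 of the 6 arrays in turn.

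**Figure D4:**
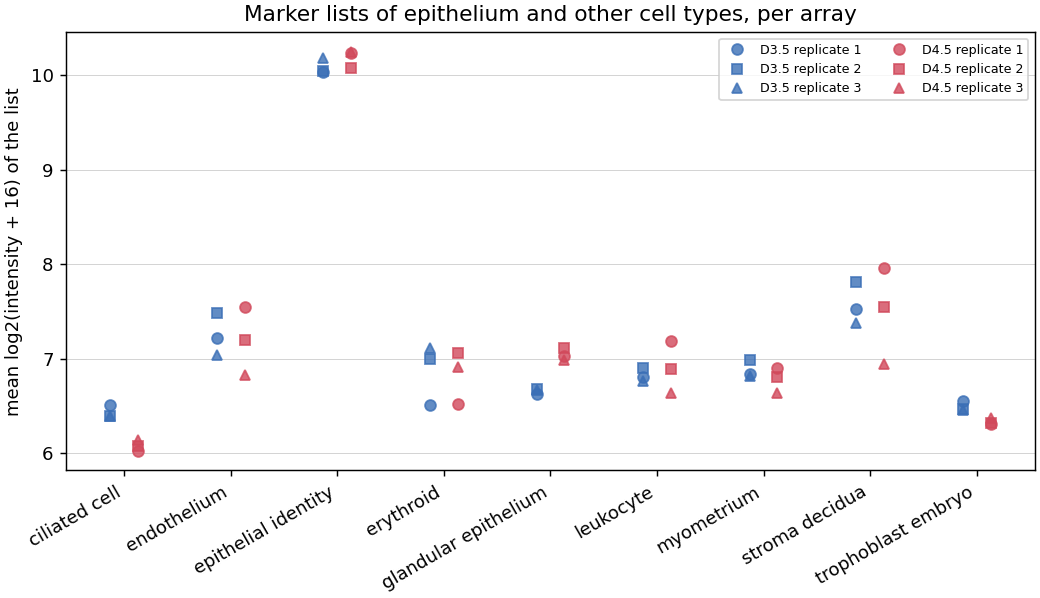
Mean log2(intensity + 16) of the epithelial list and of 8 marker lists of other cell types (horizontal axis) for each array, with D3.5 in blue, D4.5 in red and a symbol per replicate. Epithelial genes lie between 10.03 and 10.24 on every array, and the stromal list ranges from 6.95 to 7.97 within D4.5.

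The arrays separated by day. Pearson correlations across genes, which are not independent replicates, were between 0.980 and 0.993 for arrays of the same day and between 0.916 and 0.942 for arrays of different days, and the first principal component held 80.2% of the variance. D3.5 replicate 2 was nearest to the D4.5 arrays (mean r 0.940, against 0.918 and 0.928 for replicates 1 and 3).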

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

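The values as deposited, the row with the highest mean and the genes with 1 row were chosen as alternatives after seeing the data. The count of genes past the adjusted p was 9651, ran from 6562 to 9788 with each array left out in turn, and rose to 15914 in the values as deposited, where the median change of all genes was -0.40 in place of -0.07; it was 5771 among the genes above the median level, where 10870 were tested. The count with 2-fold stayed within 1.5 times of 1195 (825 to 1572 over these alternatives, 1103 to 1293 with an array left out), and 1004 of those genes were shared with the values as deposited and 947 with median centring. The number of lists past the threshold was 5, 4 to 8 with an array left out, 9 with median centring, 17 in the values as deposited, 1 among the genes above the median level and 0 with an estimated correlation. It was 14 with fry, which does not compare a list with other genes. Marker lists of other cell types went from 0 to 1 with median centring, in the values as deposited and without D4.5 replicate 3 (0 to 1 with an array left out), and to 2 with fry. The first component held 78.4% to 84.8% of the variance with an array left out, 83.3% among the genes above the median level, 84.7% in the values as deposited and 82.7% with the row of the highest mean, an alternative that sets unpaired rows against each other and moved Top2a from -0.67 to -2.27, Gjb2 from 2.95 to 4.45 and Acaca from -1.15 to -0.47. Direction turned for Car15 (-0.15), Ccdc39 (-0.21) and Tagln (-0.20) in the values as deposited, and for Dusp6 (0.15), Stat3 (0.43, past the threshold there) and Tbp (0.10) with median centring. Areg, Cdh1, Egfr, Faah, Hoxa10, Ihh, Il6st, Irg1, Klf5 and Ptgs1, without a call here, also changed sign in at least 1 alternative, without a call there. Of these, Cdh1, Egfr, Faah, Il6st, Klf5 and Ptgs1 gained a call with the same sign in another alternative, as Fst and Wnt7a did. Except for the count of fewer genes, the cause was not tested. Over named genes and alternatives 2715 values kept their sign and side of the threshold, 57 kept the sign and lost a call, 17 kept it and gained one, 15 changed sign with no call in either fit, and 6 changed sign with a call in one of them. Over the lists 601 kept direction and side, 15 lost and 37 gained a call, and 31 changed direction with no call in either. The replicate numbers did not pair the arrays (correlations of deviations -0.06, 0.06 and 0.10, and 1 of 3 D3.5 arrays correlated best with its own number); with the replicate block 8283 genes passed, 1196 with 2-fold, and 6 lists, and Calca, Car15, Ccdc39 and Twist1 lost their calls. The other deposited table gave no alternative, since it differs on 1 row without a symbol, and the analysis without a filter is the one reported. Folds are compressed for genes at the level of receptor genes on the lower day: Gabrp, Mmp7, Ttpa, Slc16a1, Slc43a2, Ereg, Inhbb, Lif, Dsc2, Il1rn, Lama1, Spink3, Pfkp, Tlr4, Ifit3, Csf1r, Tagln, Rbp4, Rdh11, Amot, Tead4 and Ascl2 among the rises, and Gpr128, B3gnt5, Dnahc5, Nrg1, Aldh1a1, Hey2, Top2a and Sox2 among the falls. Ccdc39, Hydin, Cxcl15, Myocd, Aldh1a7, Twist1, Calca and Cnr1 lay there on both days.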

Other observations

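Gene families were formed from the letters that open a symbol and tested after the list results had been seen; the tests of receptor genes, of the mixture, of stromal cells and of the level of listed genes were also chosen after the result was seen. The first test of the mixture, written before its values were seen, compared the shares of higher and lower genes (12.3 percentage points apart in replicate 2). It was replaced because replicates 1 and 3 differed by 7.56 and 9.03 themselves. Of 324 families of at least 8 genes, 9 passed with camera and the preset correlation, all higher on D4.5, and 0 passed with an estimated correlation (adjusted p = 0.947 for each of the 9). Of 8 Cct genes, which encode a chaperonin, 7 rose and none fell (mean change 0.58, adjusted p = 0.00638). Of 25 small nucleolar RNA genes (Snord) 11 rose and 1 fell (mean 0.42, adjusted p = 0.0191), of 27 Polr genes of RNA polymerases 12 rose and 4 fell (mean 0.29, adjusted p = 0.0404), of 8 Utp genes of ribosome assembly 6 rose and 1 fell (mean 0.48, adjusted p = 0.0432), and of 8 Prmt genes of arginine methylation 5 rose and none fell (mean 0.60, adjusted p = 0.0317). The others were Timm (12 genes, mean 0.37), Mettl (15, mean 0.33), Dhx (16, mean 0.35) and Eif (57, mean 0.19). Against random genes of the same level the means of Dhx and Eif lay inside the central 95% of 10000 draws (upper bounds 0.37 and 0.20), and those of the other 7 lay above it. The latter is no support, since the 9 families were picked in these same data and the draws take genes as independent. The ribosomal protein families Rpl (adjusted p = 0.992), Rps (0.418), Mrpl (0.558) and Mrps (0.0592) did not pass.

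The count of genes past the adjusted p may in part reflect separate normalization or processing of the days. Of the receptor genes 30.7% passed, against 45.2% of other genes, as a difference between the days in processing would give, so the count of 9651 cannot be read as a count of regulated genes. For the count with 2-fold, 2.38% of 210 genes of constitutive complexes passed, under the central 95% of random genes of the same level (6.67% to 14.8%). Quantile normalization over both days had already taken out most of any effect that moves genes of the same level alike. The low share therefore cannot decide whether processing had such an effect. It also cannot tell how many of the 1195 come from processing, since processing could affect other genes more. In addition, 105 of these 210 passed the adjusted p alone, and the set holds the Cct and Eif genes. Day and processing remain confounded for any gene taken by itself. The 10 splits of the 6 arrays are too few for a share under 0.05. The real split alone (1 of 10) gave as many genes, 9651 and 1195, and the highest other split gave 0 for both. Every other split has arrays of both days on each side, which adds the day difference to the spread, so the 0 is no support.

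The lists past the threshold need the same care. Of the 10 splits 8, the real one among them, gave at least as many lists as the real one (5, highest other 12). Every other split has arrays of both days on each side and so keeps part of the day difference. The splits are also too few for a share under 0.05, so they cannot decide the matter. A shift of all genes of a level between the days was examined with random lists of the same level. Their median means lay between -0.045 and 0.013, beside 0.22 to 0.45 for the 5 lists. The means of all 5 lists lay above the central 95% of 10000 such random lists. That cannot decide the matter, since quantile normalization over both days had already taken out most of such a shift. The lists were also picked in these same data, and the draws take genes as independent. Among genes above the median level 1 list passed. What stays open is that the genes of a list vary together within a day, since none of the 5 passed with an estimated correlation (0 lists). No biological explanation of the lists beyond the day itself was tested.

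D3.5 replicate 2 stood nearer to D4.5 than the other D3.5 arrays, with Atp6v0d2 at 9.57; over 147 genes at least 4-fold higher on D4.5, chosen without this array, its median lay 3.83% of the way to D4.5, and 85.0% of the genes lay toward D4.5, against medians of -0.889% and -1.68% for replicates 1 and 3. For the genes higher on D4.5 scaling is argued against, since with median centring replicate 2 stayed 5.25 percentage points above the higher of the others, but for the lower genes it stays open, as replicate 2 led with 16.1% under quantile normalization and replicate 1 with 31.8% (replicate 2 5.19%) under median centring. Also argued against is an admixture of D4.5 RNA, which would move each gene by the same share, whereas over 54 bright genes the interquartile range of the shares was 6.15 percentage points wider than in replicate 1, the wider of the others (0.909 to 9.04 over 10000 resamples), with Efhd1 at 0.4%, Prap1 at 0.7%, Atp6v0d2 at 12.5% and Cyp26a1 at 23.7%. The median share of the bright genes was 7.95% in replicate 2, against -1.14% in replicate 1 and -3.24% in replicate 3. Stromal cells remain open: the stromal list of replicate 2 lay 0.29 above the higher of the other D3.5 arrays, between the bounds set for the test, although the list was not higher on D4.5 (7.49 against 7.57, camera adjusted p = 0.889), as this explanation needs. A D3.5 sample further along toward D4.5 is a candidate explanation that the labels give no way to test.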
